A study of Mus musculus with 6 samples.

How the data were processed

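Messenger RNA was sequenced from small intestine of mice with a Kras mutation under an inducible Cre, 3 given cobimetinib and 3 given vehicle. Per the labels, mice of both sexes aged 6 to 12 weeks received 2 tamoxifen injections of 100 mg/kg on days 0 and 2, cobimetinib was given for 5 days, and tissue was taken on day 10. The series title speaks of stem cells positive for Lgr5, while the labels give small intestine as the tissue; whether whole tissue, crypts or sorted cells were used is not given in the sources used here, so levels of cell type markers cannot be read as shares of a known starting material. Libraries were stranded and sequenced as single reads of 50 bp, and all carry 1 batch label. The labels do not say that the replicates were separate animals, so p-values measure only the spread between these samples.

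The deposited files give raw exonic counts per gene, with exonic width and RPKM values that the authors computed from a library total larger than the sum of the counts. The counts column was 87.3% to 90.6% of that total. The submitters' processing notes name GSNAP and the build GRCm38.p5, and the counting tool and annotation are not given in the sources used here. The deposited counts were used, and the RPKM values only to read that total. Symbols were found for 52403 of 52636 identifiers (99.6%), and gene positions come from a GENCODE annotation of build GRCm38.

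Counts of the 6 libraries, with total counts of 18449352 to 29419801, were tested in edgeR 4.0.16 under R 4.3.3 with TMM factors, the default filter on low counts (minimum count 10, minimum total 15) and the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over 16035 genes and a threshold of 0.05. Standard errors of edgeR log2 differences, cobimetinib minus vehicle, were derived from the test statistic. CPM values use the same library scaling. Gene lists, 38 of them, were fixed before the data were examined; 36 with at least 3 genes tested were examined with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. With the correlation estimated, 0 of the 16 calls (9 higher, 7 lower) held. The fry test, which asks whether a list's genes move one way on balance, called 0, and its mixed form, which asks for change in either direction, called 1. In 3 against 3 libraries an exact permutation of labels cannot go below 0.1.

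Named genes were 24 fixed genes, the 10 largest differences each way among called genes with a mean of at least 50 counts and no overlap between groups, passing over predicted models, immunoglobulin and T cell receptor segments and pseudogenes, and up to 4 members per list, or the most abundant where none passed. As edgeR called none, the second part was applied to the calls of DESeq2 1.42.0. Members named beyond this rule were chosen after their values were seen. The libraries did not pair by replicate number. Pairs of libraries had Pearson correlations of log2 CPM from 0.793 to 0.971, and no pair agreed within sampling noise (chi-square per degree of freedom of at least 63.2). Intervals and floors cover counting error only.

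The pipeline was tested on simulated data with the means and dispersions of the 16035 genes. With 50 genes changed at each size, edgeR recovered 3 at a log2 size of 1, 24 at 2 and 48 at 5 in 6 libraries, with 7 false calls. DESeq2 recovered 6, 38 and 50 with 54 false calls. With nothing changed, edgeR called 0, DESeq2 23, and edgeR on 4 simulated libraries 28. Only genes with a mean of at least 50 counts were changed. All simulated libraries shared a single mean profile, so none stood apart as cobimetinib 1 and vehicle 1 did in the real data. These counts are therefore not rates of recovery or of false calls for the real libraries. Camera called a list of 15 genes moved by a log2 size of 1 and 0 of 36 unchanged lists. The simulated genes varied independently and list members were drawn at random. The simulation therefore gives no rate of false calls for real lists, whose members can move together. Alternatives were RLE and upper quartile factors, library totals alone, no filter, a mean of at least 50 counts, DESeq2, limma-voom, a replicate block, leaving out each library in turn, and leaving out abundant gene lists. Leaving out the first library of each group, library weights in voom and removal of a trend with gene length (loess span 0.5) were added after seeing the data.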

Results

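The samples addressed how the small intestine of mice with a mutant Kras allele differs after treatment with cobimetinib, an inhibitor of the kinases MEK1 and MEK2. In cobimetinib samples the enteroendocrine, goblet and cholesterol synthesis gene lists rose against vehicle, and the myeloid and endothelium lists fell, in a test of lists with a preset correlation. Each of these calls was lost when the correlation was estimated (adjusted p = 0.512 to 0.517 with an estimated correlation), and the endothelium call also without cobimetinib 1 and vehicle 1 (adjusted p = 0.0517). Among single genes whose groups did not overlap were Cps1 (chromosome 1, 67123026 to 67231259), the mitochondrial enzyme that starts the urea cycle, at 20.69 ± 0.22 CPM in cobimetinib and 0.65 ± 0.32 CPM in vehicle (SD, n = 3), and Anxa10 (chromosome 8, 62057042 to 62123150), an annexin of stomach epithelium, at 7.73 ± 1.34 CPM and 251.29 ± 160.1 CPM (SD, n = 3). By edgeR no single gene passed an adjusted p of 0.05 among 16035 tested: 0 genes were called higher and 0 lower, and 936 had an unadjusted p under 0.05, against 802 expected by chance. The lowest adjusted p was 0.064, for Cps1. DESeq2 called 198 genes on the same counts, of which 73 were higher and 125 lower in cobimetinib, and limma-voom called 0.

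The libraries differed within groups, and cobimetinib 1 and vehicle 1 stood apart. The first principal component held 59.0% of the variance, with scores of -149.9 for cobimetinib 1 and 96.3 for vehicle 1, while the other 4 libraries lay between 3.1 and 22.3. Cobimetinib 1 had 16490 genes with a count, and the other libraries had 20906 to 23404. Vehicle 1 had Xist at 0 CPM and Y-linked genes at 166.07 CPM in sum, whereas Xist was at 384.8 to 647.1 CPM in the other 5 libraries, so sex was not balanced between the groups. Without these 2 libraries, an alternative chosen after seeing the data, edgeR called 429 genes, 200 higher and 229 lower. Of these, 130 were shared with the 198 genes of DESeq2, all in the same direction. The DESeq2 fit included the same 4 libraries under the same labels, so this agreement was not independent. Between cobimetinib 1 and vehicle 1, which were left out, 52.2% of the 429 genes differed in the direction of the other 4 libraries. The share was 42.5% of the higher and 60.7% of the lower genes, so the pair as a whole did not repeat these calls. Leaving out vehicle 1 alone gave 4 called genes, and leaving out cobimetinib 2 gave 1.

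**Figure D1:**
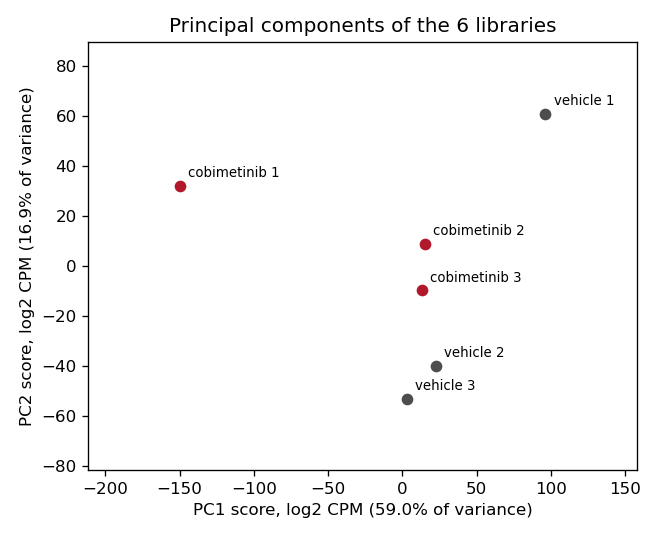
Scores of the 6 libraries on the first 2 principal components of log2 CPM, one point per library, coloured by group. Cobimetinib 1 lies at -149.9 and vehicle 1 at 96.3 on the first component, and the other 4 libraries lie between 3.1 and 22.3.

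The expression of genes that report the activity of the ERK pathway, which lies below MEK, was compared first. Of the 20 members of the ERK output list 0 passed the threshold over all genes and 0 when adjusted over the list alone, 15 had a negative and 5 a positive log2 difference, and the list was not called (adjusted p = 0.394; adjusted p = 0.786 with an estimated correlation). Its most abundant member, Emp1, was at 3586 CPM in cobimetinib and 3802 CPM in vehicle. Dusp6, a phosphatase that acts on ERK, was at 251.83 ± 104.17 and 195.28 ± 14.82 CPM (SD, n = 3), a log2 difference of 0.37 ± 0.35 (SE). Etv4, a transcription factor of the ETS family, had a log2 difference of 0.81 ± 0.30, and Spry4, a feedback inhibitor, one of -0.45 ± 0.29. The log2 differences of Spry2, Phlda1 and Etv5 were 0.36, 0.54 and -0.74. Dusp4, the member of lowest p, and Spred3, the member with the largest difference, both chosen after their values were seen, had log2 differences of -1.62 ± 0.49 and -2.95 ± 1.09. Kras was at 199.04 ± 30.72 CPM in cobimetinib and 163.1 ± 32.51 CPM in vehicle, with a log2 difference of 0.29 ± 0.29, and the counts do not tell the mutant from the normal allele. Map2k1 and Map2k2, which encode the kinases that cobimetinib inhibits, had log2 differences of 0.04 and -0.16. Ccnd1 and Myc, growth genes, had log2 differences of -0.05 and -0.14. None of these 14 genes passed the threshold, and their edgeR adjusted p lay between 0.619 and 0.982. In the simulation edgeR recovered 3 of 50 genes at a log2 size of 1, so these values do not show that the pathway was unchanged.

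Among secretory lineages of the epithelium, 3 of 4 lists rose. The enteroendocrine list, markers of hormone-producing cells, rose (adjusted p = 5.06e-10; adjusted p = 0.512 with an estimated correlation), with a median log2 difference of 1.78 over 15 genes. By edgeR 0 of its members passed over all genes, and 13 were higher and 1 lower when adjusted over the list alone. DESeq2 called 4 of them higher over all genes. Chga, a protein of secretory granules, was at 25.43 ± 7.45 CPM in cobimetinib and 6.69 ± 0.82 CPM in vehicle (SD, n = 3), a log2 difference of 1.93 ± 0.34, and it was higher in each cobimetinib library than in any vehicle library. Chgb, Nts and Gip, chosen after their values were seen, had log2 differences of 1.72, 2.37 and 1.87, while Cpe, the most abundant member, had one of -0.66. The goblet list rose (adjusted p = 0.000344; adjusted p = 0.512 with an estimated correlation). By edgeR 0 members passed over all genes and 1 was higher when adjusted over the list alone, while DESeq2 called 1 higher. Zg16, its most abundant member, was at 19891 CPM in cobimetinib 1 and 6679 and 6060 CPM in cobimetinib 2 and 3. Without cobimetinib 1 and vehicle 1, Zg16, Tff3, Agr2, Spink4 and Sytl2 had negative log2 differences (-0.08 to -0.35), and the other members positive ones. There edgeR called 3 members higher and the list stayed called (adjusted p = 0.0338, or 0.651 with an estimated correlation). Muc2, the main mucin of the gut, was at 1142.97 ± 152.42 and 600.87 ± 53.23 CPM, a log2 difference of 0.93 ± 0.28. The Paneth list rose (adjusted p = 0.0395; adjusted p = 0.681 with an estimated correlation), but without vehicle 1 its direction turned and it was not called (adjusted p = 0.536), and without cobimetinib 3 the call was lost as well (adjusted p = 0.112). Lyz1, a Paneth lysozyme, was at 63.72 CPM in vehicle 1 and at 1274.44 and 2111.55 CPM in the other vehicle libraries. The tuft list was not called (adjusted p = 0.156), and Dclk1, a tuft marker, had a log2 difference of 0.86 ± 0.50.

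**Figure D2:**
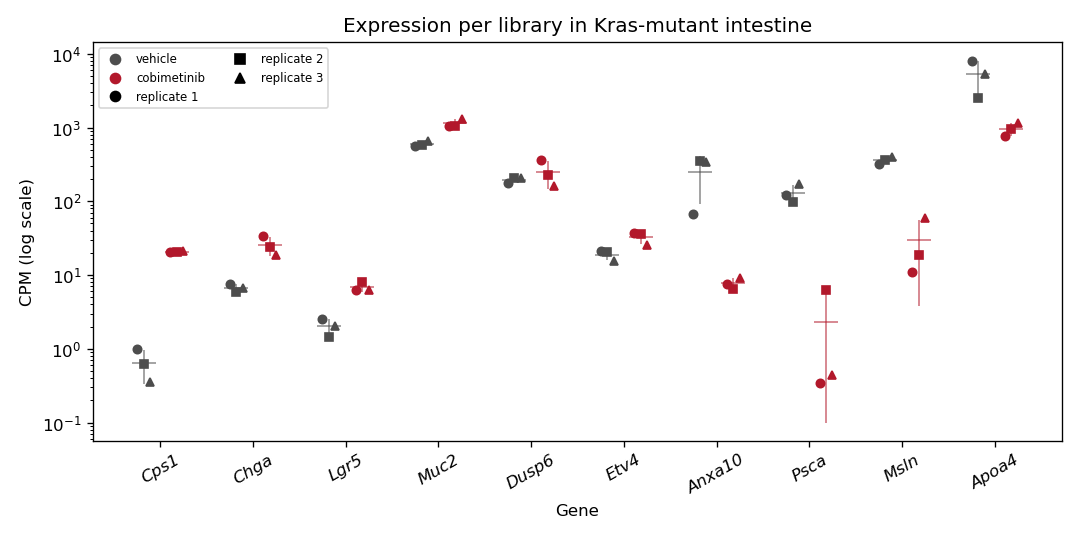
CPM on a log axis of 10 genes in each library, with markers for the replicate, a short line at the group mean and a bar of 1 SD cut off below 0.1 CPM. Cps1 lies near 20.69 CPM in cobimetinib and 0.65 CPM in vehicle, and Anxa10 near 7.73 and 251.29 CPM.

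Markers of stem and dividing cells were less uniform. Lgr5, a receptor on crypt stem cells, was at 6.82 ± 1.0 CPM in cobimetinib and 2.01 ± 0.56 CPM in vehicle (SD, n = 3), a log2 difference of 1.76 ± 0.42, with an adjusted p of 0.378 by edgeR and 0.014 by DESeq2. The Lgr5 stem cell list was not called in the 6 libraries (adjusted p = 0.156), with 1 member higher when adjusted over the list alone, and was called higher without cobimetinib 1 and vehicle 1 (adjusted p = 0.00162; adjusted p = 0.651 with an estimated correlation). Axin2, a Wnt target, had a log2 difference of 0.75 ± 0.42, and Ascl2 of -0.80 ± 1.02. In the 4 libraries left without cobimetinib 1 and vehicle 1, edgeR called Lgr5 (adjusted p = 0.0225) and Axin2 (1.34, adjusted p = 0.0174) and not Ascl2 (adjusted p = 0.761). Olfm4, at most 4.75 CPM in any library, was below the filter on low counts and was not tested. Its counts were 0, 96 and 95 in cobimetinib 1, 2 and 3, and 2, 5 and 0 in vehicle 1, 2 and 3. The Wnt target list was not called (adjusted p = 0.542). The proliferation list rose (adjusted p = 0.00548; adjusted p = 0.633 with an estimated correlation), with 21 of 25 members higher and 0 past the threshold over all genes or adjusted over the list alone, and it lost its call without cobimetinib 2 (adjusted p = 0.208) or vehicle 1 (adjusted p = 0.0786). Mki67, a marker of cycling cells, was at 62.77 ± 14.47 and 49.29 ± 9.88 CPM.

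Absorptive cells and metabolism showed differences in single programs. The cholesterol synthesis list rose (adjusted p = 0.000528; adjusted p = 0.517 with an estimated correlation), with 18 of 21 members higher and 0 past the threshold over all genes or adjusted over the list alone. Msmo1, its most abundant member, was at 898.2 CPM in cobimetinib and 565.9 CPM in vehicle. The absorptive enterocyte list was not called (adjusted p = 0.542). Alpi, an alkaline phosphatase of enterocytes, had a log2 difference of -0.17 ± 0.58, and without cobimetinib 1 and vehicle 1 it was 0.89. Apoa4, a lipoprotein component and the member of lowest p, chosen after its values were seen, was at 962.06 ± 196.37 CPM in cobimetinib and 5299.23 ± 2774.57 CPM in vehicle, and passed when adjusted over the list alone. The fatty acid oxidation list was not called (adjusted p = 0.394), with a median log2 difference of 0.02 and a mean of -0.25, and 3 members were lower when adjusted over the list alone. The mitochondrially encoded list rose (adjusted p = 0.00548; adjusted p = 0.633 with an estimated correlation), and not without vehicle 1 (adjusted p = 0.161) or cobimetinib 3 (adjusted p = 0.0889). The share of counts from these genes was 1.85%, 1.85% and 3.22% in cobimetinib 1, 2 and 3. It was 1.12%, 2% and 2.1% in vehicle 1, 2 and 3, so the groups overlapped. The list of distal intestine genes rose (adjusted p = 0.00764; adjusted p = 0.517 with an estimated correlation), while Slc10a2, its most abundant member, had a log2 difference of -0.31 ± 0.42.

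Non-epithelial cell markers moved in both directions. The myeloid list fell (adjusted p = 4.49e-05; adjusted p = 0.517 with an estimated correlation), with 10 of 10 members lower. By edgeR 0 passed over all genes and 4 were lower when adjusted over the list alone, while DESeq2 called 1 lower over all genes. The endothelium list fell (adjusted p = 0.000147; adjusted p = 0.517 with an estimated correlation), with 9 of 9 members lower and 2 lower when adjusted over the list alone, and without cobimetinib 1 and vehicle 1 its adjusted p was 0.0517. The fibroblast list (adjusted p = 0.00548; adjusted p = 0.633 with an estimated correlation) and the smooth muscle list (adjusted p = 0.0171; adjusted p = 0.633 with an estimated correlation) fell as well. The fibroblast call was lost without cobimetinib 1 (adjusted p = 0.0525), cobimetinib 2 (adjusted p = 0.152) or vehicle 1 (adjusted p = 0.131), and the smooth muscle call without cobimetinib 2 (adjusted p = 0.443), cobimetinib 3 (adjusted p = 0.0712), vehicle 2 (adjusted p = 0.0794) or vehicle 3 (adjusted p = 0.0621). The list of T cells and intraepithelial lymphocytes rose (adjusted p = 0.00308; adjusted p = 0.633 with an estimated correlation), but not without vehicle 1 (adjusted p = 0.0765). The red blood cell list rose (adjusted p = 0.00548; adjusted p = 0.633 with an estimated correlation), and not without cobimetinib 2 (adjusted p = 0.0625) or vehicle 3 (adjusted p = 0.114). The enteric neuron and B cell lists were not called (adjusted p = 0.787 and 0.156).

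Of the lists linked to injury and stress, those of YAP targets, p53 targets and fetal-like genes fell. The YAP target list fell (adjusted p = 0.000344; adjusted p = 0.633 with an estimated correlation), with 18 of 21 members lower. By edgeR 0 members passed over all genes or adjusted over the list alone, while DESeq2 called 1 lower over all genes, Nt5e. The list was not called without vehicle 1 (adjusted p = 0.0765) or without both cobimetinib 1 and vehicle 1 (adjusted p = 0.558). The p53 target list fell (adjusted p = 0.0161; adjusted p = 0.512 with an estimated correlation), with 13 of 14 members lower and 1 lower when adjusted over the list alone, and not without cobimetinib 2 (adjusted p = 0.0979) or vehicle 3 (adjusted p = 0.13). The fetal-like list fell (adjusted p = 0.0395; adjusted p = 0.517 with an estimated correlation), with 1 member lower when adjusted over the list alone, and not without cobimetinib 2 (adjusted p = 0.262), vehicle 2 (adjusted p = 0.107) or vehicle 3 (adjusted p = 0.246). That member, Msln, a surface protein of mesothelium and regenerating epithelium, was at 29.91 ± 26.14 CPM in cobimetinib and 361.63 ± 37.11 CPM in vehicle. Ly6a, a surface antigen, and Clu, a secreted chaperone, had log2 differences of 0.14 ± 0.61 and -0.47 ± 0.37. Bcl2l11, which promotes apoptosis, had one of -0.94 ± 0.61. The interferon list was not called (adjusted p = 0.0511) with a direction upward, and without cobimetinib 1 and vehicle 1 it was called in the other direction (adjusted p = 0.0338; adjusted p = 0.797 with an estimated correlation).

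The remaining lists were not called by camera in the 6 libraries. The adjusted p was 0.787 for RAS-ERK cascade components, whose median and mean log2 differences were both -0.01 while the test pointed upward, 0.163 for EGFR family genes, 0.0518 for immediate early genes, 0.297 for the Notch pathway and 0.226 for ribosome biogenesis. It was 0.542 for antigen presentation, 0.542 for the epithelial antimicrobial response, where the median log2 difference was -0.40 and the test pointed upward, 0.11 for glycolysis, 0.163 for the unfolded protein response, 0.664 for the BCL2 family and 0.297 for proximal intestine. The enteric neuron list had a median of 0.18 and a test that pointed downward. The mixed form of fry, which asks for change in either direction, called the immediate early list (adjusted p = 0.0335) and no other list. Of its 17 members 13 had a negative and 4 a positive log2 difference, and camera pointed downward. By edgeR 1 member, Dusp1, was lower when adjusted over the list alone, with a log2 difference of -1.31 ± 0.30 (SE). The form of fry for movement one way did not call the list (adjusted p = 0.181). Of the pancreatic list 0 members, and of the sex-linked list 1 member, passed the filter on low counts, so neither was tested.

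No gene met the fixed rule for naming, so the rule was applied to the genes called by DESeq2, a choice made after seeing the data. There, 55 higher and 98 lower genes met it. The 10 largest differences upward were in Cps1, Ocm, Cpn1, Dnase1, Car1, Enpp7, Rgs13, Mme, H2-T3 and Cyp2c68, with edgeR log2 differences from 4.99 for Cps1 to 2.89 for Cyp2c68. The 10 largest downward were in Prl2c3, Prl2c2, Tff1, Mucl3, Psca, Serpinb9b, Anxa10, Aloxe3, Zbtb16 and Ache. Prl2c3, a prolactin-family gene with a close paralog in Prl2c2, had 0 counts in cobimetinib and 304 in vehicle, so it was at least 77.3-fold lower against a floor of 3 counts over the group. Mucl3, a mucin-like gene, had 3 counts in cobimetinib and 375 in vehicle, a ratio of 95.3 with a 95% exact binomial interval from 32.4 to 464. Tff1, a trefoil peptide of the stomach surface, was at 0.16 ± 0.18 and 20.44 ± 18.48 CPM, and Psca at 2.34 ± 3.38 and 130.5 ± 38.23 CPM (SD, n = 3). The rule itself required no overlap between the groups, so its absence in these 20 genes is not a result. Their edgeR adjusted p lay between 0.064 and 0.540. Over all genes tested, 2009, or 12.5%, had no overlap, and chance gives 10%.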

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

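The count of 0 called genes was the same with RLE factors, upper quartile factors, library totals alone, a mean of at least 50 counts, limma-voom, and without mitochondrial, red blood cell and Paneth genes. A replicate block also gave 0 genes, with 17 lists called; deviations of same-numbered libraries did not correlate positively, so the numbers were not used as pairs. With no filter on low counts 77 genes were called (28 higher, 49 lower), and by DESeq2 198 (73 and 125). Added after seeing the data, voom with library weights called 408 (214 and 194), the fit with the length trend removed 14 (5 and 9) and the fit of 4 libraries, the first of each group left out, 429 (200 and 229). Leaving out each library in turn gave 0 to 4 genes (0 to 1 higher, 0 to 3 lower). The cause of these differences was not tested.

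Of the lists, 16 were called (9 higher, 7 lower), 0 (0 and 0) with an estimated correlation and 0 (0 and 0) by fry. The 4 libraries gave 14 called lists, 0 of them with an estimated correlation, and 9 of the 16 were called there in the same direction. Newly called were Lgr5 stem cell (0.00162), RAS-ERK components (0.0338), absorptive enterocyte (0.0463) and glycolysis (0.0338), all higher, and interferon (0.0338), lower. Of the other 7 of the 16, the Paneth list turned, and calls ended for YAP targets (0.558), T cells (0.384), fibroblasts (0.583), proliferation (0.182), mitochondrially encoded genes (0.473) and endothelium (0.0517). With the length trend removed 14 lists were called, without Paneth (0.0926) and mitochondrially encoded genes (0.0605). Leaving out each library gave 11 to 18 lists (7 to 12 higher, 3 to 7 lower). The ERK output list had an adjusted p of 0.182 to 0.96 with each library left out and was not called under any alternative run. In the 4 libraries its direction turned (adjusted p = 0.384), as did those of the Wnt target (0.215), Paneth (0.19), interferon (0.0338), antigen presentation (0.181), epithelial antimicrobial (0.0523), fatty acid oxidation (0.838) and unfolded protein response (0.301) lists; the tuft list turned with a mean of at least 50 counts (0.585). With single libraries left out, the lists named next turned in direction in some fits, and were not called in those fits. Over all such fits, turned or not, adjusted p ranged from 0.139 to 0.889 for RAS-ERK components and 0.242 to 0.844 for Wnt targets. It ranged from 0.000944 to 0.536 for Paneth, 0.0719 to 0.816 for absorptive enterocyte and 0.0676 to 0.998 for antigen presentation. The range was 0.0145 to 0.924 for the antimicrobial response and 0.0784 to 0.964 for enteric neurons and glia. Where a list turned, its adjusted p was at least 0.0719. The values under 0.05 came from fits in which the Paneth and antimicrobial lists kept their direction. The cause was not tested.

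In the 4 libraries the log2 difference changed sign for Map2k2 (0.20), Dusp6 (-0.06), Etv5 (0.29), Ccnd1 (0.05), Lyz1 (-0.57), Alpi (0.89), Ly6a (-0.85) and Bcl2l11 (0.34), and with library totals alone for Map2k1 (-0.02) and Ly6a (-0.02). With single libraries left out, the ranges that crossed 0 were -0.09 to 0.20 for Map2k1, -0.32 to 0.16 for Map2k2, 0.00 to 0.60 for Dusp6, -0.15 to 0.12 for Ccnd1, -0.47 to 0.87 for Lyz1, -0.55 to 0.53 for Alpi, -0.42 to 0.50 for Ly6a and -1.30 to 0.05 for Bcl2l11. None of these genes passed the threshold in the 6 libraries, and the cause was not tested. Of the fixed genes and those chosen from the DESeq2 calls, 15 kept their direction and passed the threshold in the 4 libraries. The scaling moved the median log2 difference of all genes by less than 0.1.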

Other observations

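A few genes typical of gastric epithelium were far higher in vehicle than in cobimetinib intestine. Anxa10, Tff1, Psca, Mucl3 and Vsig1, all picked from among genes called by DESeq2 after their values were seen, had a median log2 difference of -5.79, and edgeR called 0 of the 5 in the 6 libraries and 4 without cobimetinib 1 and vehicle 1, where Psca did not pass. A list of 8 stomach genes stayed under the filter on low counts, at no more than 1.15 CPM in any library. Fabp6, an ileal bile acid binding protein, lay between 660.26 and 5173.18 CPM in cobimetinib and between 0.45 and 138.1 CPM in vehicle, a log2 difference of 6.08 ± 1.94 (adjusted p = 0.643 by edgeR). Zbtb16, Tsc22d3, Sgk1 and Pdk4 are among 8 glucocorticoid-induced genes noticed among those called lower by DESeq2, with a median log2 difference of -1.92 that their choice fixed as negative, and edgeR called 0 of the 8 in the 6 libraries and 7 without cobimetinib 1 and vehicle 1, where Klf15 did not pass. Of the 8, Pdk4 and Angptl4 also belong to the fixed fatty acid oxidation list and Dusp1 to the immediate early list. Their levels therefore do not single out a glucocorticoid response.

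The tests of gene length, sex, stomach tissue, gut position, ileum, and the first library of each group were chosen only after the results were seen. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. By edgeR the real split gave 0 genes and the highest other split 0, so 10 of 10 gave as many. DESeq2 gave 198 genes in the real split and 231 in the highest other, the split that exchanges cobimetinib 1 with vehicle 1, so 2 splits gave as many. Voom with library weights gave 408 and at most 151 in another split, so 1 split gave as many. Camera called 16 lists in the real split, again 1 split with as many. It also called 7 to 14 lists in every other split, so many list calls arose under any grouping of the libraries. The 4 libraries left without cobimetinib 1 and vehicle 1 have only 3 splits into 2 and 2, also too few: the real one gave 429 genes by edgeR and 14 lists, and the others 0 and 3 genes and 12 and 10 lists.

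Cobimetinib 1 and vehicle 1 stood apart from their groups. Gene length as the whole cause is argued against, since the smaller of the 2 ratios of distances stayed at 1.62 with the length trend removed. For cobimetinib 1, sequencing depth is argued against as the cause of its fewer detected genes. With the other libraries thinned to its total, the smallest, it had 0.79 of the genes of the lowest of them. Depth was not tested for vehicle 1. Sex does not account for cobimetinib 1, whose Xist was 1.07 times the lowest other cobimetinib library, while for vehicle 1, with a ratio of 0, sex and the library cannot be told apart. An exchange of the labels of the pair stays open. Of the 429 genes called in the other 4 libraries, 52.2% differed within the pair in the direction of those libraries. This share lay between the bounds set for either answer, and was 42.5% of the 200 higher genes and 60.7% of the 229 lower genes. Cps1 and the gastric-type genes followed the labels. They were picked from calls made under these labels, so they cannot weigh against an exchange. No biological explanation other than sex was tested.

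The gastric-type genes may reflect a difference in epithelial identity between the treatments, as a hypothesis that was not itself tested. Stomach tissue in the vehicle samples is argued against, since 8 abundant stomach transcripts together reached at most 0.00556 of Anxa10 in a vehicle library. The first library of each group is argued against for 4 of the 5 genes, which passed in the other 4 libraries with adjustment over all genes tested (median log2 difference of the 5 -5.44), although that fit was chosen after seeing the data. The position of the sampled segment stays open: Gata4, a proximal gene, reached in vehicle 2 and vehicle 3 at most 0.22 of the highest cobimetinib library, but was at 33.77 CPM in vehicle 1, the highest of the 6 libraries, and the proximal list had a median log2 difference of -1.42. Likewise for Fabp6, Slc10a2, another ileal gene, had a log2 difference of -0.31, while the median of the distal list was 0.69 (adjusted p = 0.00764; adjusted p = 0.517 with an estimated correlation), so these single genes do not exclude less ileum in vehicle.

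A lower glucocorticoid response in cobimetinib is a candidate explanation for the lower levels of these 8 genes. Of 6 further targets, written down before their values were seen, 5 were lower, which met the bound set in advance, but 0 of the 6 passed a test by edgeR or DESeq2. So few genes, which may move together, can meet that bound by chance. Each of the 5 lower targets had its highest value in vehicle 1. Without the first library of each group the 6 further targets had a median of -0.36 and 4 were lower, so for these the difference may rest on cobimetinib 1 and vehicle 1. For 7 of the 8 noticed genes those libraries are argued against, as these passed without them (median of the 8 -1.49). Stress of the animals was not measured.

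A lower upper-villus program was also tested as a hypothesis, from 5 genes noticed for their negative log2 differences, of which edgeR called 0 in the 6 libraries. DESeq2 called Apoa4, Ada, Nt5e and Slc28a2 and not Egfr, whose log2 difference was -0.25 without the first library of each group. In that fit, chosen after seeing the data, edgeR called 4 of the 5, all but Egfr. Of 6 further upper-villus genes written down before their values were seen, 4 were lower, between the bounds set for either answer, and 2 were lower without the first library of each group. The test did not decide.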
